A study of Sus scrofa with 6 samples.

How the data were processed

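Total RNA from 6 pools of 50 porcine oocytes, 3 before and 3 after 44 h of maturation in culture at 38 °C under 5% CO2, was measured on Affymetrix arrays after 2 rounds of amplification from 100 ng of RNA, per the labels' protocols. The design text also mentions a dye test used to sort oocytes into groups, and the labels of single samples do not assign it, so it was not used here. The titles call the first group in vivo oocytes, and the descriptions place it before maturation in culture. The deposited table holds log2 expression values made by the authors with RMA, a method that as usually run subtracts background, quantile-normalizes the arrays and summarises probes, per the submitters' processing notes. The version of RMA, its options and any filter on probes are not given in the sources used here. That the scale is log2 was inferred from RMA and the range of values. The values were not centred per gene. Direction is not at issue on arrays of 1 colour. Array medians were 5.62, 5.63 and 5.64 after maturation for replicates 1, 2 and 3, and 5.70, 5.69 and 5.67 before it.

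Probes were named from the platform annotation, updated through gene identifiers to the RefSeq table of assembly Sscrofa11.1, from which only names were taken. Of 12258 probes 10848 had 1 gene symbol, 342 had several and 1068 had none listed. Of those with 1 symbol 1041 carried only a locus or Ensembl name, which left 9807 probes of 9763 named genes. For the 43 genes with more than 1 probe the brightest stood for the gene, and 0 of these genes had probes called in opposite directions. Detection calls were not analysed here, so no level is stated to be above background.

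All probes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), after minus before maturation, with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. A 2-fold change is a log2 difference of 1. The 19 gene lists were tested with camera at a preset correlation of 0.01 on 1 probe per named gene, adjusted over the lists. Of these 11 were called lower and 0 higher, and 0 calls held with an estimated correlation, while at an adjusted p under 0.05 fry called 12. That correlation was estimated from only 6 arrays, so a call lost with it does not show that a list was unchanged. The adjusted p of 0.236 shared by several lists came from unadjusted camera p-values of 0.0437 to 0.0992. List medians are given relative to the median of all named genes (0.08) where so stated. Members counted as measured are those matched by name, such as 23 of 58 oxidative phosphorylation genes and 18 of 37 immediate early genes. The others may be absent from the array's table or stand there under another name. The test, the lists, the rule for named genes and the alternatives were fixed before the data were examined. That rule named the 10 largest increases and 10 largest decreases that passed the test with no overlap between arrays. It also named up to 4 members per list with the smallest p among those called (the 2 smallest where fewer than 2 passed), and 10 fixed genes of which 8 were in the table. CCNB1 and CYP19A1 were not analysed here. It gave 82 genes. Genes named beside a count outside this rule (PTX3, VCAN and RUNX1) were chosen after their values were seen.

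Same-numbered arrays of the groups deviated together from their group means, with correlations of 0.283, 0.120 and 0.142, and each array correlated best with its own number. By this criterion the numbers pair the arrays, which is a hint from the data, since the labels say only that they are biological replicates. The fit without the block was kept, as fixed, and the blocked fit is given where it changes a call of a list or named gene. Replicates differed by a median of 0.125 to 0.168 between arrays of a group, so none was a copy of another.

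The fit was tested on simulated data of the same size for this comparison. With 40 probes per size it called 40 at a log2 change of -2, 39 at -1, 36 at 1, 10 at 0.5 and 8 at -0.5, and 6 unchanged probes. On 9763 genes drawn independently of each other camera found the 1 shifted list and called 0 others. The simulated spread came from the fit's own model. The simulation therefore cannot show how camera behaves where genes are correlated. The alternatives were the replicate block, 4 other scalings, filters on dim probes, other models of the spread, 1 probe per gene, a test against a 1.5-fold change, other list tests and leaving out each array. Tables were handled with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.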

Results

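Gene expression was measured in porcine oocytes before and after maturation in culture, with 3 arrays in each group and 12258 probes per array. Each array held RNA of a pool of 50 oocytes from pubertal Landrace gilts. The matured pools came from cumulus-oocyte complexes, oocytes enclosed in their somatic cumulus cells, kept for 44 h in medium with follicular fluid and gonadotropins. The median log2 level per array lay between 5.62 and 5.70. Correlations across probes were 0.994 to 0.995 among arrays after maturation, 0.989 to 0.993 among arrays before it, and 0.965 to 0.983 between the groups. Genes are not independent replicates, so these correlations only describe the arrays. The first principal component held 71.2% of the variance and separated the groups, with replicate 3 before maturation farthest out. The number of arrays limits the precision of every value.

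The only comparison of the design asks which transcripts differed in level between oocytes before and after maturation in culture. Only the matured pools were cultured, so maturation cannot be told apart from the culture and its medium. On the deposited scale, changes of at least 2-fold were mostly decreases, with 43 probes higher and 392 lower. A scaling that holds ribosomal protein genes level gave 1763 higher and 132 lower. By construction it adds the same amount to every probe's difference, and it moved the median probe from 0.08 to 0.80. It assumes that ribosomal protein genes did not change, although their median lay at -0.64 relative to all genes. The transcript with the largest measured decrease was PTER, a phosphotriesterase-related gene, whose log2 level went from 9.30 ± 0.45 to 3.98 ± 0.10 (SD, n = 3), a measured 39.9-fold lower level. The measured level of CD55, which encodes a complement regulator, fell 29.9-fold, and that of HSD17B1, which encodes an enzyme of oestradiol synthesis, fell 21.3-fold. The largest measured increases were those of HSD3B1, which encodes an enzyme of progesterone synthesis (15.4-fold, from 4.25 ± 0.12 to 8.20 ± 0.42), and NTRK3, which encodes a neurotrophin receptor (12.5-fold, from 4.77 ± 0.03 to 8.41 ± 0.09). The limma adjusted p of these 5 genes lay between 9.14e-07 and 2.12e-05. The rule named only genes for which all 3 arrays of one group lay beyond all 3 of the other. After maturation PTER and CD55 lay under the arrays' lower quartiles (4.33 to 4.45), and before it HSD3B1 lay close to them (4.27 to 4.30). Background was not assessed, so the folds and the order of genes with such a dim group are not exact, and a true fold can be larger than the measured one.

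The other named genes with the largest measured decreases were ID2 (-3.99), an inhibitor of DNA binding, BTG2 (-3.75), an antiproliferative gene, RASL11B (-3.70), CYR61 (-3.63), a matrix-associated signalling gene, ESR1 (-3.61), the oestrogen receptor alpha gene, ITM2A (-3.59) and EDA (-3.57), each given as the log2 difference after minus before. The other large increases were CTSC (2.57), a cysteine protease gene, HAPLN1 (2.51), whose product links hyaluronan to proteoglycans, TM4SF1 (2.42), ADGRG6 (2.34), FAM78B (2.02), FAM83B (2.01), DAB2 (2.003) and the chemokine gene CXCL12 (1.98). Standard errors of these differences ran from 0.12 for EDA to 0.33 for ADGRG6. Groups did not overlap for any of them, which the rule for naming them required. ESR1 and ITM2A after maturation and HAPLN1 and CXCL12 before it also lay under the lower quartile of each array. TM4SF1, ADGRG6, FAM78B and FAM83B lay close to it before maturation, with means of 4.24, 4.29, 4.25 and 4.34.

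Of the 12258 probes, 394 were called higher and 989 lower after maturation at a limma adjusted p under 0.05. The median probe differed by 0.08 on the log2 scale, by 0.00713 with cyclic loess and by 0.136 with a common median. Arrays of the groups did not overlap for 2659 probes in the higher direction and 1762 in the lower, 36.1% of all, where chance gives 10%. Decreases made up 71.5% of the calls, against 80.6% with cyclic loess, 59.2% after a second quantile normalization, 49.3% with each array at a common median and 2.74% with the ribosomal protein genes held level. With the replicate number as a block, 621 probes were called higher. The count of higher probes was 103, 119 and 204 without replicate 1, 2 or 3 after maturation, and 258 and 166 without replicate 2 or 3 before it. The count of lower probes was 531 and 545 without replicate 1 or 2 after maturation. The p-values measure the spread between pools labelled as biological replicates, and an exact permutation test of 3 arrays against 3 cannot give a two-sided p under 0.10.

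**Figure D1:**
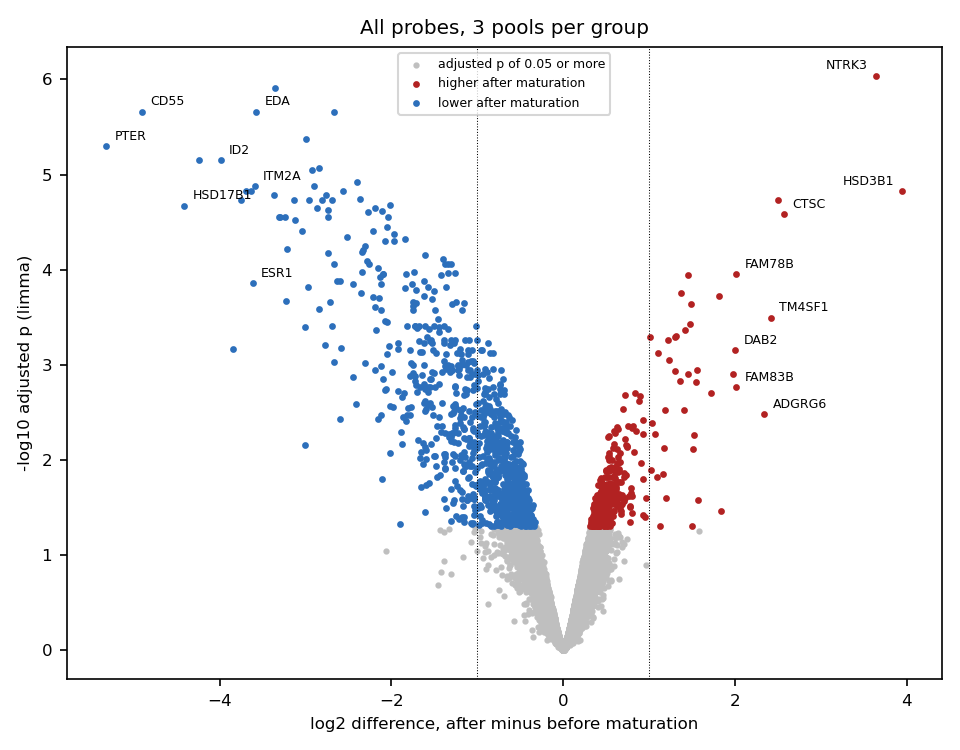
Each point is a probe, with the log2 difference after minus before maturation on the x axis and the negative log10 of the limma adjusted p on the y axis, for 3 pools per group. Of the probes beyond the dotted lines at a 2-fold change, 392 were called lower and 43 higher, and some of the 20 genes with the largest changes are named.

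Most oocyte-specific transcripts did not pass the test, in a share close to that of all probes, of which 10875 of 12258 were not called. Of 26 measured genes 0 were called higher, 3 lower and 23 neither, and adjusted over the list alone 3 were lower as well. BMP15 and GDF9, which encode growth factors secreted by the oocyte, had log2 levels of 12.07 ± 0.04 and 11.01 ± 0.03 before and 12.19 ± 0.01 and 11.06 ± 0.04 after maturation (adjusted p = 0.395 and 0.681). MOS, a kinase gene of the meiotic arrest pathway, differed by 0.04 (adjusted p = 0.800). With ribosomal protein genes held level these 3 were called higher (0.83, 0.77 and 0.76). KIT fell by 1.22, and the zona pellucida genes ZP3 fell by 0.70 and ZP4 fell by 0.40 (adjusted p = 0.0104 and 0.0343). Under that scaling KIT, ZP3 and ZP4 were not called, although ZP3 and ZP4 had positive values. ZP4 was also not called without any 1 of the 6 arrays. The list's median lay 0.02 above that of all genes (camera adjusted p = 0.842), and below it without replicate 3 of either group. Most of these genes were bright, with a median level at percentile 98.5 of all probes. BMP15 lay near the arrays' highest values (12.51 to 12.65), and saturation of bright probes was not assessed.

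Markers of cumulus and granulosa cells, the somatic cells around the oocyte, fell as a list but did not move together. Of 20 measured genes 10 fell, 2 rose and 8 did not pass the test, and adjusted over the list alone 12 fell and 3 rose. SERPINE2, a protease inhibitor gene, fell by 2.92, GJA1, the gap junction gene connexin 43, fell by 2.27 from 10.91 ± 0.18 to 8.64 ± 0.17, and HSD17B1 and ESR1 fell as given above. HSD3B1 and GSTA1, a glutathione transferase gene, rose by 3.95 and 1.30. GSTA1 belongs to a family of near-identical copies, so its level is uncertain. The list's median lay at -0.70 relative to all genes (camera adjusted p = 1.86e-06, adjusted p = 0.236 with an estimated correlation).

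Genes of cumulus expansion, the formation of a hyaluronan matrix around the oocyte, held several of the larger increases. Of 19 measured genes 5 rose, 2 fell and 12 did not pass the test, and adjusted over the list alone 6 rose and 2 fell. HAPLN1 rose by 2.51, the hyaluronan synthase gene HAS2 (listed as SHAS2) by 1.72, the hyaluronan receptor gene CD44 by 1.21 and the prostaglandin synthase gene PTGS2 by 1.11. Before maturation HAPLN1, HAS2 and PTGS2 lay under the lower quartile of each array, with means of 3.90, 3.84 and 4.03, so their measured increases are not exact. PTX3 was the remaining gene called higher, and VCAN and RUNX1 were those called lower. As a list they did not pass the test against other genes (camera adjusted p = 0.0691). They did so without the dimmest 25% of probes (adjusted p = 0.00826), with ribosomal protein genes held level (adjusted p = 0.00284) and with trend and robust set (adjusted p = 0.0452), where other alternatives gave up to 0.986, and fry, which tests the list by itself, gave an adjusted p of 0.00204.

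**Figure D2:**
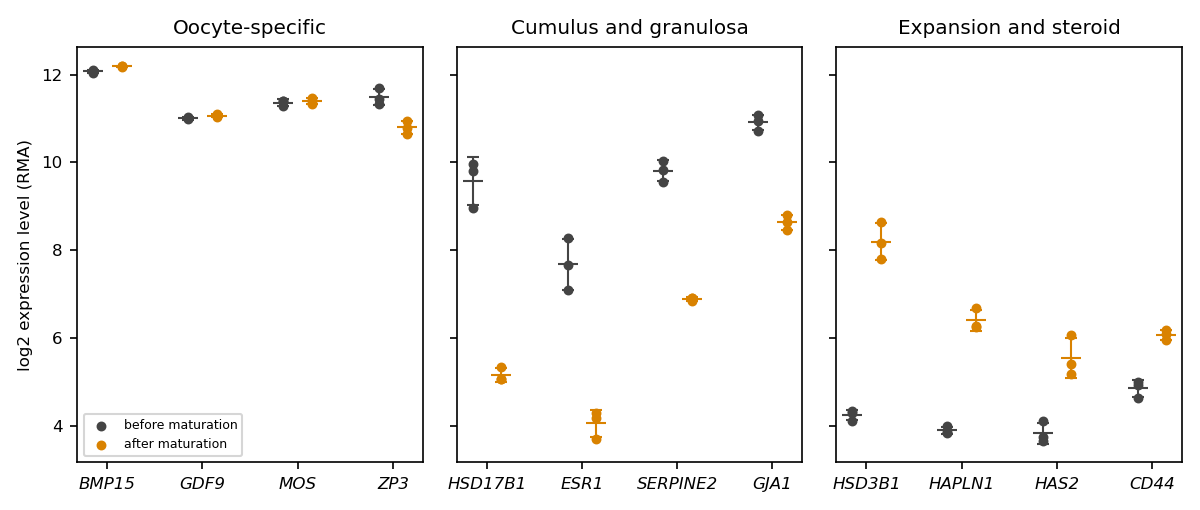
Log2 expression levels of 12 genes on each of the 6 arrays, with points for single pools, horizontal marks for group means and bars for 1 SD (n = 3). BMP15, GDF9 and MOS lay at about the same level in both groups. ZP3, HSD17B1, ESR1, SERPINE2 and GJA1 lay lower after maturation, and HSD3B1, HAPLN1, HAS2 and CD44 lay higher.

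Lists of markers of other cell types were not called by camera, and endothelial and leukocyte markers had few calls. Of 17 theca and stromal markers 2 rose and 1 fell, with POSTN at 1.20, COL3A1 at 0.37 and the smooth muscle actin gene ACTA2 at -1.93, and adjusted over the list alone 3 rose and 1 fell (camera adjusted p = 0.811). The theca and stromal median was -0.03 relative to all genes while its mean and test pointed upward, and it turned to 0.044 without replicate 3 after maturation and 0.036 without replicate 1 before it. Of 9 endothelial markers 0 were called with limma, also when adjusted over the list alone, and SOX17 and KDR had values of 0.51 and 0.23 (camera adjusted p = 0.0691). Of 14 leukocyte and erythroid markers CD3E rose by 0.48 and TYROBP had a value of 0.41, and adjusted over the list alone 0 were called (camera adjusted p = 0.0691). SOX17, KDR and TYROBP were called higher with ribosomal protein genes held level, and SOX17 also with the replicate block (0.51, adjusted p = 0.0369). The endothelial and leukocyte medians of 0.15 and 0.10 relative to all genes became 0.081 and 0.049 without replicate 2 after maturation. POSTN, COL3A1 and CD3E lost the call without replicate 1 after maturation and without some other single arrays. Before maturation POSTN, COL3A1 and KDR lay under the lower quartile of each array (means of 3.69, 4.04 and 3.47). KDR stayed under it after maturation (3.71).

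Immediate early genes, which respond rapidly to stimuli, showed the lowest median of the lists. Of 18 genes matched by name 7 fell and 0 rose, each of the 7 by at least 2-fold, and adjusted over the list alone 12 fell. CYR61 (-3.63), an older name of the list's gene CCN1, was not matched. The counts and tests of this list therefore leave it out. BTG2 fell by 3.75, ATF3 fell by 2.96, JUN fell by 2.12 and MCL1, a survival gene of the BCL2 family, fell by 2.03. The median lay at -1.23 relative to all genes (camera adjusted p = 2.65e-08, adjusted p = 0.236 with an estimated correlation). Of the 20 cumulus and granulosa markers 10 fell beside them, with a median of -0.70 relative to all genes (adjusted p = 0.236 with an estimated correlation).

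Meiotic regulators mostly did not pass the test, like the probes as a whole (10875 of 12258 not called). Of 35 cell cycle genes 2 fell and 1 rose, also when adjusted over the list alone. CCNE2, a cyclin E gene, fell by 2.98 and WEE1, a kinase gene that restrains CDK1, fell by 2.12, and RPS6KA2 rose by 0.48. CDK1 had log2 levels that differed by -0.04 (adjusted p = 0.912), and this difference became 0.68 with ribosomal protein genes held level. The list's mean was -0.07, its median 0.07 and its test pointed upward (camera adjusted p = 0.811). Of 16 cohesin and recombination genes STAG2 fell by 0.74, MSH4 fell by 0.50 and 0 rose, with 2 also adjusted over the list alone (camera adjusted p = 0.150). With ribosomal protein genes held level STAG2 and MSH4 were not called, and MSH4 had a positive value. Of 22 genes of maternal mRNA storage and decay DDX6 fell by 0.62 and KHSRP had a value of 0.33. Under the same scaling DDX6 was positive but not called, and KHSRP was called higher. Adjusted over the list alone 0 were called (camera adjusted p = 0.765). RPS6KA2, STAG2, MSH4 and DDX6 lost the call without replicate 1 after maturation and without some other single arrays.

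Genes of glycolysis and of the cytosolic ribosome fell as lists. Of 15 glycolysis genes 7 fell and 0 rose, and adjusted over the list alone 11 fell. PGK1 fell by 1.99, the regulatory gene PFKFB3 fell by 1.79, TPI1 fell by 1.05, GPI fell by 0.91 and GAPDH, often used as a reference gene, fell by 0.88. With ribosomal protein genes held level TPI1, GPI and GAPDH were not called (-0.33, -0.20 and -0.16). The glycolysis median lay at -0.76 relative to all genes (camera adjusted p = 2.79e-06, adjusted p = 0.236 with an estimated correlation). Of 41 ribosomal protein genes 22 fell and 0 rose, and adjusted over the list alone 27 fell. RPS3A fell by 1.11, RPS13 fell by 0.996, RPS23 fell by 0.91 and RPL12 fell by 0.68. Under a scaling that holds ribosomal protein genes level by construction RPS3A, RPS13, RPS23 and RPL12 were not called, and RPL12 turned to 0.03. The ribosomal median lay at -0.64 relative to all genes, which that scaling leaves unchanged (on the deposited scale camera adjusted p = 6.68e-14, adjusted p = 0.236 with an estimated correlation). Cumulus and granulosa markers, with 10 of 20 called lower and a median of -0.70 relative to all genes, moved in the same direction as both lists (adjusted p = 0.236 with an estimated correlation). Ribosomal protein genes have many near-identical copies, so their single levels are uncertain.

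Chaperone and antioxidant genes fell as lists, by smaller amounts. Of 29 chaperone genes 10 fell and 0 rose, and adjusted over the list alone 12 fell. HSPA4 fell by 1.18, SERPINH1, a collagen chaperone gene, fell by 1.098, HSPA5 fell by 0.99 and HSPA8 fell by 0.47. With ribosomal protein genes held level HSPA4, SERPINH1, HSPA5 and HSPA8 were not called, and HSPA8 had a positive value. HSPA8 was also not called without replicate 1 after maturation. The chaperone median lay at -0.29 relative to all genes (camera adjusted p = 2.79e-06, adjusted p = 0.199 with an estimated correlation). Of 29 antioxidant genes 10 fell and 1, GSTA1, rose, and adjusted over the list alone 12 fell and 3 rose. NQO1 fell by 1.70, TXNIP, an inhibitor of thioredoxin, fell by 1.49, and PRDX6 fell by 1.01, the last not called with ribosomal protein genes held level. The antioxidant median lay at -0.18 relative to all genes (camera adjusted p = 0.00913, adjusted p = 0.238 with an estimated correlation), and the call ended with the dimmer probes left out (adjusted p = 0.0518). This median was -0.30 without replicate 3 after maturation and -0.12 without replicate 2 before it. The cumulus and granulosa marker median of -0.70 (adjusted p = 0.236 with an estimated correlation) had the same direction as both lists.

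Matrix and TGF-beta superfamily genes moved both ways, with more decreases. Of 29 matrix and adhesion genes 11 fell and 3 rose, and adjusted over the list alone 12 fell and 3 rose. LAMB2, a laminin gene, fell by 1.84 and CDH2, the N-cadherin gene, fell by 1.76, while FN1, the fibronectin gene, rose by 1.42 and the integrin gene ITGA5 by 1.45. The matrix median lay at -0.25 relative to all genes (camera adjusted p = 0.00424, adjusted p = 0.238 with an estimated correlation), and at -0.43 without replicate 2 before maturation. Of 34 TGF-beta superfamily genes 10 fell and 2 rose, and adjusted over the list alone 10 fell and 5 rose. ID2 fell by 3.99, the co-receptor gene TGFBR3 fell by 2.35, the activin antagonist gene FST fell by 2.15 and the activin subunit gene INHBA fell by 2.05. FST and INHBA also stand in the list of cumulus and granulosa markers, whose median lay at -0.70 (adjusted p = 0.236 with an estimated correlation), in the same direction as the matrix list, and 5 of the 34 genes stand in another list. The TGF-beta median was 0.01, its mean -0.39 and its test pointed downward (camera adjusted p = 0.0388, adjusted p = 0.236 with an estimated correlation). Among other settings that call ended with the replicate block (adjusted p = 0.0551) and without replicate 1 before maturation (adjusted p = 0.0504). Relative to all genes its median of -0.068 became -0.10 without replicate 3 after maturation and -0.0056 without replicate 3 before it.

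Of 15 cholesterol synthesis genes 3 fell and 0 rose, also adjusted over the list alone, with SC5D at -1.92, ACAT2 at -0.94 and STARD4 at -0.77 (camera adjusted p = 0.0477, adjusted p = 0.394 with an estimated correlation). ACAT2 and STARD4 were not called with ribosomal protein genes held level. Among other settings the cholesterol call ended without replicate 2 or 3 after maturation (adjusted p = 0.0769 and 0.0864) and without replicate 2 or 3 before it (adjusted p = 0.126 and 0.101). The cholesterol median of -0.11 relative to all genes became -0.17 and -0.24 without replicate 1 after and before maturation, and -0.051 without replicate 3 before it. Of 23 oxidative phosphorylation genes 3 fell and 1 rose, and adjusted over the list alone 9 fell and 2 rose. NDUFA2 fell by 0.99, NDUFB3 fell by 0.66 and NDUFS1 fell by 0.65, and NDUFA8 rose by 0.64. With ribosomal protein genes held level NDUFA2, NDUFB3 and NDUFS1 were not called, although NDUFB3 and NDUFS1 had positive values. The oxidative phosphorylation median lay at -0.26 relative to all genes (camera adjusted p = 0.00913, adjusted p = 0.387 with an estimated correlation), and among other settings the call ended without replicate 2 before maturation (median -0.17, adjusted p = 0.0712). Of 20 apoptosis genes 3 fell and 0 rose, and adjusted over the list alone 5 fell. MCL1 fell by 2.03, FAS fell by 0.72 and BID fell by 0.62. Under the same scaling FAS and BID were not called, and BID had a positive value. The apoptosis list was called lower (camera adjusted p = 0.0162, adjusted p = 0.236 with an estimated correlation). This call ended with the dimmer probes left out (adjusted p = 0.103). The apoptosis median of -0.17 relative to all genes became -0.099 without replicate 2 after maturation. The lists in this paragraph had the same direction as the cumulus and granulosa markers (median -0.70, adjusted p = 0.236 with an estimated correlation). STARD4, NDUFB3, NDUFA8, NDUFS1 and BID lost the call without replicate 1 after maturation and without some other single arrays.

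**Figure D3:**
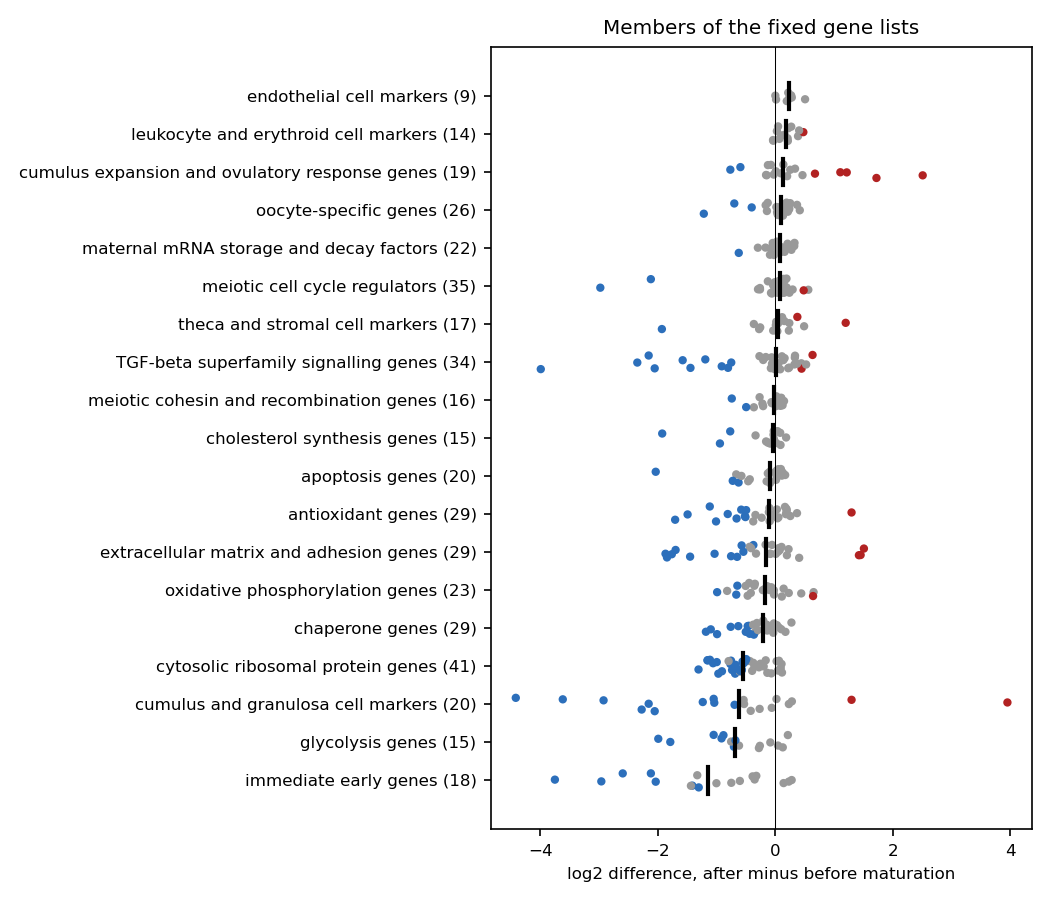
Log2 differences after minus before maturation of the members of the 19 gene lists that were matched by name, one point per gene, red where called higher, blue where called lower and grey otherwise, with a black bar at each list's median and the number of members in parentheses. The lowest median was that of immediate early genes at -1.15, and that of ribosomal protein genes was -0.56. A scaling that holds ribosomal protein genes level removes the latter value by construction. It leaves their median of -0.64 relative to all genes unchanged.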

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

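The alternatives were planned, and the cause of a change was not tested except where the construction of the alternative shows it. The 394 higher calls became 621 with the replicate block, 596 after a second quantile normalization, 915 with a common median, 254 with cyclic loess, 211 with the dimmer 50% of probes left out, 27 in the treat test against a 1.5-fold change and 103 to 434 with 1 array left out. The 989 lower calls became 222 in the treat test and 531 to 1013 with 1 array left out. Of the 2-fold calls, 23 higher were left without the dimmer probes, and 27 higher and 222 lower in the treat test. Holding ribosomal protein genes level gave 10201 higher and 287 lower calls, 1763 and 132 at 2-fold, and moved the median probe from 0.08 to 0.80, so list values are relative to all genes. This scaling adds the same amount to every probe's difference, so sign changes under it follow from that shift. The fits with and without the block shared 1335 calls, all in the same direction, with 48 found only without the block and 512 only with it. The block also ended the TGF-beta list's call (-0.068), changed no other list's call and among named genes called only SOX17 in addition (0.51). The TGF-beta call further ended with cyclic loess (-0.089) and without the dimmer probes (-0.050), with a range of -0.10 to -0.0056 over arrays left out. The cholesterol call ended after quantile normalization (-0.093), with a common median (-0.11), cyclic loess (-0.10), ribosomal scaling (-0.11), without the dimmest 25% (-0.099) or 50% (-0.069) of probes and with fry (-0.11), with a range of -0.24 to -0.051 over arrays left out. The oxidative phosphorylation call ended with ribosomal scaling (-0.26), without the dimmer probes (-0.20) and with fry (-0.26), with a range of -0.37 to -0.17 over arrays left out. Calls held but medians moved by over 1.5 times for matrix genes without the dimmest 25% or 50% of probes (-0.45 and -0.43), for cumulus markers without the dimmer 50% (-1.18), for TGF-beta genes after quantile normalization (-0.13) and without the dimmest 25% (-0.13), and for antioxidant (-0.12) and apoptosis (-0.11) genes after quantile normalization. Without the dimmer probes the antioxidant (-0.15) and apoptosis (-0.19) calls ended. The cumulus expansion list was called higher with ribosomal scaling (0.056), without the dimmest 25% (0.39), with trend and robust set (0.056) and with fry (0.056), and fry also called the endothelial (0.15) and leukocyte (0.10) lists. With 1 array left out these medians ran from 0.035 to 0.090, 0.081 to 0.17 and 0.049 to 0.13, the lowest without replicate 3 before maturation for expansion genes and without replicate 2 after it for the other lists. Uncalled lists near 0 changed sign, with ranges of -0.066 to 0.044 for theca and stromal, -0.014 to 0.019 for oocyte-specific, -0.041 to 0.010 for meiotic cell cycle and -0.033 to 0.019 for maternal mRNA genes. With an estimated correlation the calls of cumulus markers (-0.70), immediate early (-1.23), cholesterol (-0.11), glycolysis (-0.76), oxidative phosphorylation (-0.26), ribosomal (-0.64), TGF-beta (-0.068), matrix (-0.25), chaperone (-0.29), antioxidant (-0.18) and apoptosis (-0.17) genes ended. The estimate rests on 6 arrays, so these losses do not show that the lists were unchanged. Under ribosomal scaling ZP3 (0.020), ZP4 (0.32), MSH4 (0.22), DDX6 (0.096), NDUFB3 (0.053), NDUFS1 (0.072), RPL12 (0.034), HSPA8 (0.25) and BID (0.093) changed sign and lost the call. CDK1 (0.68) changed sign and was called higher. With the sign kept, KIT, STAG2, ACAT2, STARD4, TPI1, GPI, NDUFA2, RPS3A, RPS13, RPS23, HSPA4, HSPA5, SERPINH1, PRDX6, FAS and GAPDH lost the call, and SOX17, KDR, TYROBP, KHSRP, GDF9, BMP15 and MOS gained it. Over the 82 named genes, 1222 of 1366 values kept direction and side of the threshold, and 114 lost the call and 14 gained it with the sign kept. A further 10 changed sign with a call in at least 1 of the fits compared, and 6 uncalled values changed sign. Of 74 called named genes 60 kept the call with any 1 array left out, and ZP4, POSTN, COL3A1, CD3E, RPS6KA2, STAG2, MSH4, DDX6, STARD4, NDUFB3, NDUFA8, NDUFS1, HSPA8 and BID did not (14, 11 and 10 lost without replicates 1, 2 and 3 after maturation, 4, 8 and 10 before it). A planned log transform with a floor was not run, since the values were on a log scale. Signal over background was not measured, which limits statements on dim probes.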

Other observations

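The tests of explanations in this part, and the gene families and single genes in this paragraph, were all chosen after the results were seen. Genes were grouped by the stem of their symbols, and of 51 families with at least 15 measured members 4 were called by camera. Besides the RPL and RPS stems, which largely repeat the ribosomal list, these were the EIF stem (28 members, 5 lower and 0 higher, median -0.27 relative to all genes, adjusted p = 0.00635) and the COL stem (29 members, 2 higher and 0 lower, median 0.11, adjusted p = 0.0469). For each of these 2 stems the adjusted p was 0.652 with an estimated correlation. A stem is not a pathway. The RPS stem also holds kinase genes, among them RPS6KA2, its only gene called higher. The EIF stem holds translation initiation factors and also kinases and binding proteins (EIF2AK1, EIF2AK2, EIF2AK3, EIF4EBP2 and EIF4ENIF1), and the COL stem holds COL4A3BP, a ceramide transfer gene, beside collagens. The scaling alternatives were not run on families. Of the 5 lower EIF genes EIF2AK3 fell by 1.26 and EIF2AK1 fell by 0.91, both kinase genes, EIF3A fell by 1.19, EIF2B2 fell by 0.55 and EIF3L fell by 0.50. COL15A1 rose by 0.38 and COL3A1 by 0.37. Of 154 microRNA genes 4 were called higher and 1 lower. Among single genes, the WNT antagonist genes DKK1 and DKK2 rose by 1.37 and 1.49, and NANOG and SOX9, transcription factor genes, rose by 1.31 and 1.81. These single genes are outside the 82 named genes. Other scalings and arrays left out were not examined for them, and they form no tested list.

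The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1383 changed probes and the highest other split 0, and at 2-fold 435 and 0, so 1 split reached each count. The 3 other splits that part all same-numbered pairs also gave 0. Every split except the real one mixes the groups, so a difference between the groups widens the spread within it. The 0 calls of those splits are therefore no reference for chance.

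The median probe lay 0.08 higher after maturation, 0.00713 higher with cyclic loess and 0.136 with a common median, while the arrays' own medians were lower after maturation (5.62 to 5.64) than before it (5.67 to 5.70). Background that lifts dim probes was tested on uncalled probes, where the dimmest 25% exceeded the brightest 25% by 0.00292 (95% bootstrap interval -0.00678 to 0.0119), while the dimmer 50% exceeded the brighter 50% by 0.0348 (0.0253 to 0.0429). From the dimmest to the brightest 25% the medians were 0.085, 0.142, 0.0509 and 0.0821, and without the dimmer 50% the median of all probes was 0.0425, so these values do not settle it. Rescaling of unchanged probes by normalization may contribute as well, and neither can be told apart here from a broad biological shift. A common median raised the higher calls from 394 to 915, while cyclic loess lowered them to 254, so the number of small increases depends on the scaling in both directions and no value decides it.

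Cumulus and granulosa cell markers had a median of -0.70 relative to all genes (camera adjusted p = 1.86e-06, adjusted p = 0.236 with an estimated correlation), and of the 39 genes in the cumulus marker and expansion lists 6 were called at least 2-fold higher and 9 at least 2-fold lower. Of the 20 markers 3 also stand in another list, and the brightest called marker before maturation was GJA1 at 10.91. How many of these genes the oocyte itself expresses and how many cumulus cells each pool held were not tested. Fewer cumulus cells in the matured pools, a cumulus expansion response in cells left on the oocytes and changes in the oocyte all stay open. Effects of the culture itself, with its gonadotropins and follicular fluid, stay open as well, since only the matured pools were cultured. The same holds for the falls of the other lists and of the EIF stem, and no explanation was tested.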
